A study of Mus musculus with 3 samples.

How the data were processed

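RNA from whole skin of FVB mice, an inbred laboratory strain, was measured at 3 ages, embryonic day 18.5 (E18.5), postnatal day 3 (P3) and 10 weeks. Per the labels' protocols, RNA was extracted with Trizol and sequencing libraries were made with the Illumina TruSeq RNA kit from 1 ug of total RNA. The series design speaks of 2 biological replicates per age, whereas the tables used here hold 1 value per gene and age, headed as an average. Values of single animals, and any spread between them, were not used here, so that no standard deviation, interval or p-value could be attached to any value, and no difference below has a replicate check.

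The deposited values are FPKM, fragments per transcript length and number of mapped fragments, per the file headers. Per the submitters' processing notes, TopHat2 2.0.7 and Cufflinks 2.1.1 were used with the mouse genome build mm9. The gene annotation, the strand setting, the read numbers and the treatment of reads that match several genes are not given in the sources used here. Sequencing depth is therefore unknown, and the precision of low values cannot be stated. FPKM is a share of each library, so that a large change in a few abundant genes moves all others. The 10 highest genes held 8.75% of the summed FPKM at E18.5, 7.97% at P3 and 7.86% at 10 weeks. The 100 highest held 36.6%, 34.1% and 31.6%. Failed estimates, described below, are not in these shares. They include Krt1, Krt10 and Eef1a1 at P3 and Col3a1 at E18.5, so that the ages are not strictly comparable here. Rows of short RNA genes, such as microRNA and small nucleolar RNA genes, held 7.95%, 6.73% and 6.19%. A gene shorter than the sequenced fragments has an unreliable FPKM, and such rows are named only where a sentence says so.

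Each table listed 21881 gene rows, of which 21877 occurred in all 3. A few rows hold several symbols that share reads. The status column of the tables marked some genes of very high or failed estimation, and 3 such values at E18.5 and 7 at P3 were listed at 0. These were treated as failed estimates and left out, never read as an absence of RNA. They were Col3a1, Hrnr and Snord85 at E18.5, and Ddx19b, Eef1a1, Flg2, Hrnr, Krt1, Krt10 and Tchh at P3. A further 24 values at E18.5 bore a failure mark with a value above 0 and were kept. An unmarked 0 can also be a failed or undivided estimate, since Hmgcs1, an enzyme of sterol synthesis that cells in general use, was listed at 0 at all 3 ages. Genes at 0 are therefore called listed at 0, and no fold is given for them. Families with near-identical members, here the stefin A, Lce, Sprr, Krtap, alpha and beta globin, H2, Ftl and Rnaset2 genes and the neighbouring BC100530 and BC117090, are uncertain gene by gene, because shared reads can be divided differently in each library. Overlapping and antisense genes carry the same caution. So do keratins listed with a shared span, such as Krt6a and Krt6b (chromosome 15, 101346119 to 101524736).

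Coordinates are those of the tables, in mm9. The tables count starts from 0, judged from 523 microRNA genes: end minus start equalled the RefSeq gene length in 219 of them, and end minus start plus 1 did so in 3. For this reason 1 was added to each start. The reference available here is of another build and was used only for gene synonyms and for transcript length and GC content.

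The 3 ages were compared pairwise. The measure was log2 of (FPKM + 1) at the later age over (FPKM + 1) at the earlier, among genes with at least 1 FPKM at 1 or more ages. The pseudocount of 1 understates the change of low genes. A gene is called higher or lower at a difference of at least 1, that is 2-fold on this scale, and "higher" and "lower" without a value always refer to this rule. A gene is highest or lowest at an age when it passes the same threshold against both other ages. Each age has 1 value, which enters 2 of the comparisons, so an error in the P3 value of a gene would appear in both with opposite sign. The test with replicates that had been foreseen for tables with replicate columns was not used.

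Gene lists for cell types, tissue layers and processes of skin were fixed before the data were examined: 41 lists with 865 entries, 829 distinct genes. Of the entries, 856 were found, 847 by symbol, 6 by an older symbol and 3 in a shared row, and 9 were not matched, Flg and Col6a3 among them. Of the 820 rows matched, 35 belong to more than 1 list. The median difference of a list's expressed members is given with the central 95% of the medians of 10000 random lists of the same size, matched on mean expression in 20 bins (seed 1). This describes where a list stood among the genes of these libraries. It is not a test across animals. A list is said to lie outside, above or below the random lists when its median lay outside that central range. The marker lists of muscle, fat, blood, immune, vessel, nerve and pigment cells show other cell types that a piece of whole skin holds.

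Genes are named by a rule fixed at the same time: per comparison the 8 largest rises and 8 largest falls among genes with at least 10 FPKM at either age, without short RNA, unnamed, mitochondrial and multi-row symbols; in each list up to 4 members with the largest difference in the main direction and up to 2 that passed 2-fold the other way; Trp63, Krt5, Krt14, Krt1, Krt10, Lor and Mki67 in every case; every keratin and p53-family gene; and the 10 genes of highest FPKM per age. Genes named outside this rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

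The alternatives tried were pseudocounts of 0.1 and 5, other minimum values, 3 other scalings (the median of ratios over genes expressed at all ages, the upper quartile, and the sum left after removing muscle, erythroid, hair and white adipocyte lists and the 100 highest genes of any age), thresholds of 1.5-fold and 4-fold, rows with 1 symbol only, removal of short RNA genes with failed and low-data genes, and the mean in place of the median of a list. Counting failed values as 0, leaving out chromosomes X and Y and leaving out the lists of muscle, fat, blood, immune, vessel and nerve cells were added after seeing the data. So was the use of the pseudocount of 5 for lists. Leaving out replicates was planned for tables with replicate columns and could not be run.

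The calls were tested on simulated data. For P3 against E18.5, 200 of 13476 simulated genes were changed, with a spread of 0.2 (SD, log2 scale) put on every gene. The changed genes were drawn only from those with at least 5 FPKM at E18.5, so the recovery does not speak for lower genes. The 2-fold rule called 100% of genes raised 4-fold, 100% of genes lowered 4-fold, 0% of genes changed 1.5-fold and 0% of unchanged genes. With a spread this small against the threshold, the result for unchanged genes was set by the simulation. Of 400 lists drawn at random from all genes of the same simulation, changed ones included, 3% fell outside the central 95%. The spread between real animals is unknown and may be larger than the simulated one. Computations used Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots used matplotlib 3.10.9.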

Results

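Gene expression was measured by RNA sequencing in whole skin of FVB mice just before birth (E18.5), in the first days after it (P3) and in adulthood (10 weeks), with 1 averaged FPKM value per gene and age. The title of the series names p63, the transcription factor that stratified epithelia depend on, and the transcriptome of mouse skin. The 3 pairwise comparisons ask which genes differ in level between late embryonic, newborn and adult skin. Because no values of single animals were used, no difference below could be set against a spread between replicates, and depth is unknown. A total of 14662 genes reached 1 FPKM at 1 or more ages, and 12094 of them (82.5%) did so at all 3. The number of genes at or above 1 FPKM was 13388 at E18.5, 12886 at P3 and 13779 at 10 weeks, with 345, 236 and 783 genes reaching it at that age alone. Genes of very high FPKM at E18.5 included Krt10 (4499 FPKM), the elongation factor Eef1a1 (4369 FPKM) and Stfa3, a cystatin-type protease inhibitor (7273 FPKM). Among the highest at P3, where the estimates of Krt10, Krt1 and Eef1a1 failed, was again Stfa3 (7296 FPKM). Others were Krtdap, a secreted product of differentiating keratinocytes (5735 FPKM), and the cornified envelope protein loricrin, Lor (5378 FPKM). At 10 weeks they included the muscle genes Acta1 (4107 FPKM) and Tnnc2 (3756 FPKM), the fat and muscle carbonic anhydrase Car3 (4023 FPKM), and Apoe (3302 FPKM).

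Trp63, the gene of p63 (mm9 chromosome 16, 25683851 to 25892174), stood at 43.4 FPKM at E18.5, 83.0 at P3 and 44.4 at 10 weeks, a log2 difference of 0.92 from E18.5 to P3 and of -0.89 from P3 to 10 weeks, both under the 2-fold threshold. Its relative Trp73 stood at 3.86, 6.49 and 1.83 FPKM, and Trp53 at 38.6, 46.4 and 29.0 FPKM. The basal-layer keratin pair followed the same course with larger differences. Krt5 (chromosome 15, 101537501 to 101543322) was at 1058, 2638 and 816 FPKM, and Krt14 (chromosome 11, 100064476 to 100068824) at 952, 2439 and 646 FPKM, so that both were higher at P3 than at either other age. Krt15, a basal keratin abundant in the hair follicle bulge, instead had its largest value in the adult, with 488, 726 and 969 FPKM. Of the suprabasal pair, Krt1 was at 3688 FPKM at E18.5 and 267 FPKM at 10 weeks, and Krt10 at 4499 and 1430 FPKM; their P3 estimates failed. Krt77, a suprabasal keratin of the same cluster as Krt1 (chromosome 15, 101690287 to 101700049), went the other way, from 18.7 FPKM at E18.5 to 224 at P3 and 963 at 10 weeks. In the adult its FPKM thus exceeded that of Krt1, whereas at E18.5 it was far below.

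**Figure D1:**
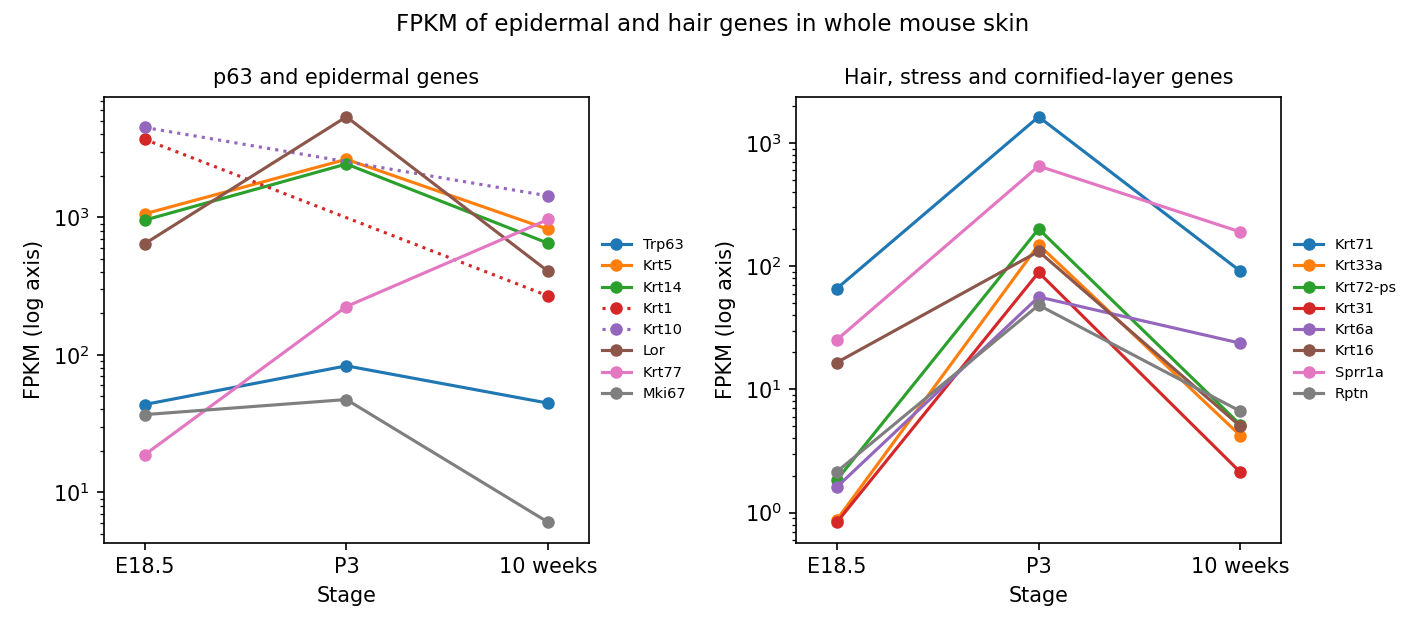
FPKM on a log axis at each of the 3 ages, 1 averaged value per point, for p63 and epidermal genes (left) and for hair, stress and cornified-layer genes (right); dotted lines join E18.5 and 10 weeks where the P3 estimate failed (Krt1 and Krt10). Lor and the hair keratins peak at P3 (Lor 5378 FPKM), whereas Krt77 goes from 18.7 to 963 FPKM and Mki67 from 36.7 to 6.04 FPKM.

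Between E18.5 and P3, genes of the differentiating epidermis, the epidermal lipid barrier and above all the hair shaft were higher after birth, while genes of muscle, fat, vessels, mast cells and dermal matrix were lower. Of 14653 genes compared, 1401 were higher at P3 and 1380 lower. Of the 8 largest rises, 7 were genes of the keratin-associated proteins that embed the keratins of the hair shaft, led by Krtap22-2 (0.173 to 396 FPKM), Krtap15 (listed at 0, then 300 FPKM) and Krtap16-10 (0.0263 to 257 FPKM). The largest falls included the cardiac-type actin Actc1 of embryonic muscle (216 to 3.44 FPKM), Thrsp, a regulator of fat synthesis (288 to 6.80 FPKM), and Hdc, the histamine-forming enzyme of mast cells (77.9 to 1.53 FPKM). Stfa1 (354 to 1.53 FPKM), Hba-a2, Ftl2 and Rnaset2b also belonged to this group, but each has near-identical relatives, and their levels are uncertain.

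Textbook p63 targets and their family were shifted upward at P3: 22 of 35 expressed members were higher and 0 lower, with a median log2 difference of 1.29 (central 95% of random lists -0.12 to 0.34). Zfp750, a p63-dependent regulator of terminal differentiation, stood at 17.4 FPKM at E18.5 and 90.5 at P3, the homeobox gene Dlx3 at 15.9 and 75.1, Klf4 at 57.3 and 245, and the envelope protein gene Evpl at 17.6 and 75.6. Suprabasal and desmosome genes were higher in 17 of 18 cases (median 1.88), among them Cdsn (52.8 to 328 FPKM) and the cross-linking enzyme Tgm1 (18.1 to 89.7 FPKM). Granular and cornified-layer genes were higher in 27 of 28 (median 1.70). Lor (chromosome 3, 91884193 to 91887064) was 641 FPKM before and 5378 after birth, Rptn 2.15 and 48.3, and Lce1f 101 and 587. Basal-layer and hemidesmosome genes were shifted less, with 5 of 15 higher, 0 lower and a median of 0.69; Col17a1 was at 30.1 and 89.7 FPKM. Small proline-rich envelope proteins were higher in 9 of 11 (median 1.49), with Sprr1a at 25.3 and 650 FPKM and Sprr4 at 11.5 and 340, and 1 was lower, Sprr2a1, listed at 0 at P3. Lipid barrier genes were higher in 15 of 22 (median 1.55), including the lipid transporter Abca12 (14.5 to 68.0 FPKM) and the very-long-chain elongase Elovl4 (67.1 to 291 FPKM). Keratins of stress and periderm were higher in 6 of 9 (median 1.21), with Krt6a at 1.61 and 56.3 FPKM and Krt16 at 16.5 and 132. In the same pair of ages the muscle, adipocyte, endothelial and dermal matrix lists moved down, as given below, and FPKM values share a total.

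The hair shaft and inner root sheath list had the largest median of any list at P3, 4.17, with 34 of 35 members higher and 0 lower. Krt33a stood at 0.874 and 149 FPKM, Krt31 at 0.834 and 89.0, and Krt72-ps, as the tables call it, at 1.84 and 201. All 45 expressed Krtap genes were higher at P3 than at E18.5 and all 45 were lower again at 10 weeks, with median levels of 0.117, 42.4 and 0.574 FPKM. This count was added after the values were seen. Genes of hair follicle signalling were mostly not shifted (6 of 26 higher, 1 lower, median 0.16, inside the random lists). Foxn1 (1.80 to 11.4 FPKM), Msx2 (6.06 to 29.9) and Hoxc13 (6.31 to 27.6), regulators of hair differentiation, were among the higher ones, and the Wnt inhibitor Dkk1 was the lower (3.47 to 0.533). Hair follicle stem cell genes went both ways, 3 of 17 higher and 3 lower. Their median of 0.45 lay above the random lists, a call that is lost with the mean of the members or a pseudocount of 5. Pigment cell genes were higher in 8 of 15 (median 1.07), with Mlana at 12.2 and 81.8 FPKM. Sebaceous gland genes were higher in 11 of 23 and lower in 4 (median 0.77), a list call that is lost with a pseudocount of 5. Fa2h, Elovl3 and Awat1 were among the higher, Awat1, a wax synthase, at 1.10 and 13.4 FPKM. Cidea and Pparg, which fat cells also express, were lower.

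Muscle, adipocyte, endothelial, macrophage, mast cell, dermal matrix, fibroblast and pericyte lists lay below the random lists at P3, to different extents. Adult skeletal muscle genes were lower in 27 of 29 cases with a median of -2.90, including creatine kinase Ckm (456 to 26.3 FPKM) and the myosin light chain Mylpf (1697 to 116 FPKM). Embryonic and neonatal muscle genes were lower in 14 of 18 (median -2.82), with Myh3 at 44.0 and 1.03 FPKM. White adipocyte genes were lower in 14 of 21 (median -1.41), with Car3 at 1898 and 343 FPKM. Brown adipocyte genes were lower in 4 of 7 (median -2.19), with the uncoupling protein Ucp1 at 64.5 and 2.54 FPKM. Endothelial genes were lower in 13 of 16 (median -1.44), macrophage genes in 12 of 18 (median -1.27) and mast cell genes in 8 of 11 (median -1.81), the mast cell proteases Cpa3 and Cma1 going from 331 to 23.1 and from 404 to 33.0 FPKM. Dermal extracellular matrix genes were lower in 19 of 30 (median -1.18), among them lumican, Lum (349 to 95.8 FPKM), and the microfibril gene Mfap2 (165 to 55.7 FPKM). Tenascin C, Tnc, was higher (9.92 to 23.3 FPKM), a call that is lost under upper-quartile scaling and with a pseudocount of 5. Fibroblast lineage genes were lower in 6 of 16 (median -0.89), with Twist2 at 63.2 and 13.8 FPKM, and pericyte genes in 3 of 11 (median -0.59). MHC class II genes were higher in 5 of 10 (median 1.11), H2-Aa going from 7.68 to 64.1 FPKM and the invariant chain Cd74 from 12.6 to 96.2. Of the class I genes 0 of 15 passed 2-fold; their median of -0.37 lay just below the random lists, a call that is lost with the median of ratios, a minimum of 5 FPKM, the mean or a pseudocount of 5. Cd207, a lectin of Langerhans cells, stood at 0.0146 and 3.82 FPKM, in a list with 2 of 11 members higher (median -0.23, inside the random lists).

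Imprinted growth genes were lower at P3 in 18 of 22 cases and higher in 2, with a median of -1.81 (random lists -0.22 to 0.37). The muscle, adipocyte, fibroblast and dermal matrix lists also lay below the random lists, as given above. Dlk1 belongs to the fibroblast list as well. The growth inhibitor Cdkn1c stood at 206 FPKM at E18.5 and 19.9 at P3, the non-coding Meg3 (chromosome 12, 110779206 to 110809939) at 288 and 26.8, and its neighbour Dlk1 (110691033 to 110701546) at 163 and 10.9. The 2 higher ones, Nnat and Phlda2, pass 2-fold with the deposited scaling but with none of the 3 others, nor with a pseudocount of 5. The list moved further by 10 weeks, when 9 of 22 were lower than at P3 and 4 higher (median -0.58). With a pseudocount of 5, 8 were lower and 2 higher than at P3. Against E18.5, 17 were lower and 1 higher (median -2.34). Igf2, the fetal growth factor (chromosome 7, 149836673 to 149856261), went from 394 to 88.5 and 4.52 FPKM over the 3 ages, and H19 from 2090 to 749 and 164, whereas Nnat went from 8.83 to 19.2 and 138.

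Sex-linked genes differed between the same ages. The Y-linked Eif2s3y, Ddx3y and Uty were at 42.1, 24.1 and 7.50 FPKM at E18.5 and at 0.0838, 0.0218 and 0.00366 FPKM at P3, and Kdm5d was at 7.13 FPKM and then listed at 0. Xist was at 0.0433 FPKM at E18.5 and 64.6 at P3. At 10 weeks Xist was at 73.0 FPKM and all 4 Y-linked genes were listed at 0. The comparisons with E18.5 are therefore also comparisons between a library with a male pattern of these genes and libraries with a female pattern. Without chromosomes X and Y, 1375 genes were higher and 1296 lower at P3 than at E18.5. Scaling the ages on the median of ratios would shift log2 ratios of FPKM by -0.12 in this comparison, -0.10 from P3 to 10 weeks and -0.22 from E18.5 to 10 weeks, and the log2 differences of low genes by less. List ranges, which are set by other genes of the same comparison, contain most of such a shift. With the upper quartile, the share of called genes that were higher at P3 moved from 50.4% to 37.4% (1101 higher, 1842 lower). A pseudocount of 5 left 842 genes higher and 626 lower, without Cd207, Dkk1 and Sprr2a1; with it 4 of 11 small proline-rich, 5 of 15 pigment cell and 3 of 10 MHC class II genes were still higher and 7 of 18 macrophage and 8 of 16 endothelial genes lower. A pseudocount of 0.1 gave 2155 lower.

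**Figure D2:**
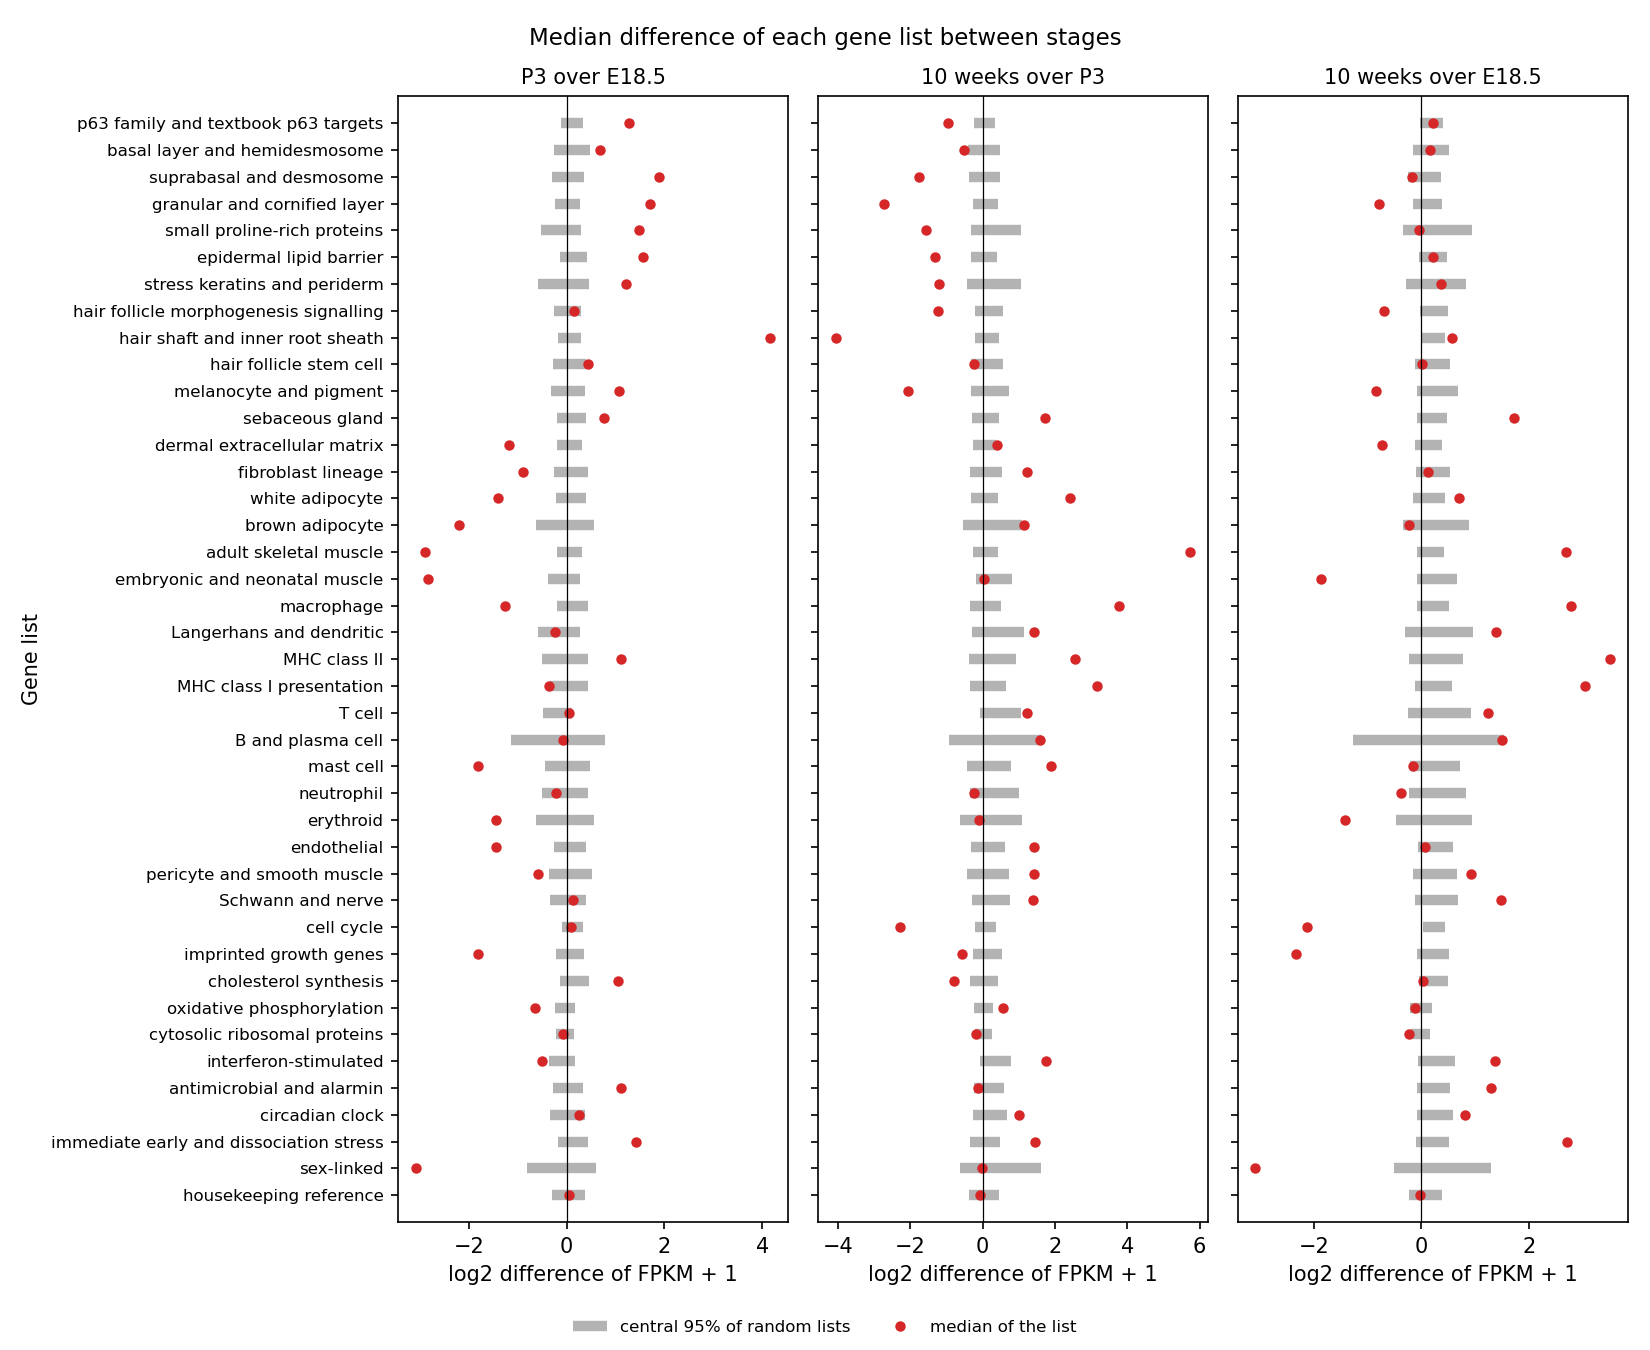
Median log2 difference of FPKM + 1 over the expressed members of each of the 41 gene lists (points) in the 3 comparisons (panels), with the central 95% of medians of 10000 expression-matched random lists (grey bars). Hair shaft genes have a median of 4.17 at P3 over E18.5 and -4.07 at 10 weeks over P3, while adult skeletal muscle genes have -2.90 and 5.74.

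From P3 to 10 weeks the picture turned: keratinocyte differentiation, hair shaft and cell cycle genes were lower in the adult, and genes of muscle, fat, macrophages and antigen presentation were higher. Of 14655 genes compared, 2909 were higher at 10 weeks and 1462 lower. The largest rises were in the calcium buffer of fast muscle Pvalb (2.53 to 2123 FPKM), Hamp2 of the hepcidin family (0.0105 to 587), the fast myosin Myh4 (chromosome 11, 67051531 to 67073948; 1.32 to 837), the chemokine Ccl8 (2.16 to 660.5), the calcium pump Atp2a1 (6.03 to 1290), Retnla, a product of alternatively activated macrophages and fat tissue (18.7 to 2905), Tcap (2.93 to 570) and Ifitm6 (0.218 to 174). Among the largest falls, Stfa3 went from 7296 to 7.17 FPKM, BC100530 from 3750 to 1.98, Lce1g from 314 to 1.68 and the serpin Serpinb3a from 77.1 to 0.0864, while Stfa2 and Krtap16-4 were listed at 0 in the adult. At E18.5 Stfa3 had stood at 7273 and BC100530 at 5176 FPKM, so that both were already abundant before birth. Members of this stefin cluster share reads, but Stfa3, BC100530, BC117090 and Stfa2 were all low or at 0 in the adult.

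Members of the p63 family and target list were lower in 16 of 35 cases and higher in 0 (median -0.97, random lists -0.24 to 0.35). Dlx3 stood at 75.1 and 8.03 FPKM and the grainyhead factor Grhl3 at 40.8 and 10.1. The list holds Trp63, Trp73 and Trp53 themselves, with Trp73 among the lower. It shares members such as Krt5, Krt14 and Evpl with the basal and suprabasal lists, so their shifts are not separate observations. Suprabasal genes were lower in 16 of 18 (median -1.76), among them Tgm3 (46.4 to 0.508 FPKM) and involucrin, Ivl (326 to 43.8), and 1 was higher, Krt77. Cornified-layer genes were lower in 27 of 28 (median -2.74), including Lor (5378 to 403 FPKM) and Casp14, the protease of cornification (286 to 8.39). Small proline-rich genes were lower in 8 of 11 (median -1.57), Sprr1b going from 61.2 to 0.201 FPKM. Lipid barrier genes were lower in 13 of 22 (median -1.33), with the lipoxygenases Alox12b at 85.7 and 8.72 FPKM and Aloxe3 at 49.0 and 6.84. Basal-layer genes were lower in 6 of 15 and higher in 1 (median -0.52); the list lay below the random lists by its median but inside them by its mean. Stress and periderm keratins split, with 5 of 9 lower, Krt16 (132 to 5.01 FPKM) and Krt6b (24.7 to 0.725) first, and 3 higher, among them the simple-epithelial keratins Krt19 (2.44 to 20.7) and Krt18 (3.03 to 11.7). Krt6b shares its listed span with Krt6a, so its level alone is uncertain. Muscle, fat and several immune lists were higher in the same comparison, as given below.

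Hair shaft genes were lower in 33 of 35 cases and higher in 0 (median -4.07), with Krt33a at 149 and 4.21 FPKM. Hair follicle signalling genes, a list whose median had lain inside the random lists at P3, were lower in 16 of 26 and higher in 0 (median -1.24). Examples are Lef1 (17.1 to 1.66 FPKM), Shh (8.78 to 0.982) and Msx2 (29.9 to 3.34). Hair follicle stem cell genes again went both ways, with 2 of 17 higher and 4 lower (median -0.23, inside the random lists). Cd34, carried by bulge stem cells and also by vessels and fibroblasts, was higher (30.2 to 323 FPKM), and Lhx2 lower (35.8 to 12.1). Pigment cell genes were lower in 11 of 15 (median -2.07), with Pmel at 51.2 and 3.17 FPKM and Dct at 82.3 and 8.60, and Ednrb was higher (14.0 to 49.6). Sebaceous gland genes were higher in 13 of 23 and lower in 2 (median 1.73). The higher ones included the desaturases Scd3 at 2.09 and 66.0 FPKM and Scd1 at 107 and 1223, and the wax synthase Awat2 at 7.25 and 125. They also included Cidea (25.6 to 86.9 FPKM) and Pparg (10.6 to 39.6), which fat cells express too. White adipocyte genes were higher in the same comparison, as given below. Proliferation genes were lower in 33 of 36 and higher in 0 (median -2.29), although from E18.5 to P3 none of the 36 had differed 2-fold. Mki67 (chromosome 7, 142881471 to 142908062) was at 36.7, 47.2 and 6.04 FPKM at the 3 ages, Cdc20 at 29.9, 42.8 and 4.89, and Top2a at 59.5, 68.8 and 9.83.

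Adult skeletal muscle genes were higher at 10 weeks in 28 of 29 cases and lower in 0, with a median of 5.74, the largest of any list. Embryonic and neonatal muscle genes had a median of 0.04. Their largest rise was in desmin, Des (10.8 to 450 FPKM), a member of the adult muscle and pericyte lists as well. Of 18, 6 were higher and 4 lower, such as Myh8 (13.5 to 1.36). With a pseudocount of 5, 2 were higher and 1 lower. White adipocyte genes were higher in 19 of 21 (median 2.41), including the adipsin gene Cfd (76.4 to 2131 FPKM) and Thrsp (6.80 to 200). Brown adipocyte genes were higher in 4 of 7 and lower in 2 (median 1.14), a list call that is lost with the mean or a pseudocount of 5, and Ucp1 stood at 2.54 and 0.0308 FPKM. With a pseudocount of 5, 1 of the 4, Ppargc1a, and the lower Ucp1 and Elovl3 do not pass 2-fold. Macrophage genes were higher in 17 of 18 (median 3.76), with lysozyme Lyz2 at 21.3 and 1002 FPKM and the complement genes C1qa at 16.6 and 487 and C1qb at 10.8 and 387. MHC class II genes were higher in all 10 cases (median 2.56) and class I presentation genes in all 15 (median 3.15), H2-Aa going from 64.1 to 1014 and B2m from 114 to 2510 FPKM. Langerhans and dendritic cell genes were higher in 9 of 11 (median 1.41), among them Cd209a (0.282 to 60.1 FPKM) and the Langerhans cell lectin Cd207 (3.82 to 24.3). T cell genes were higher in 13 of 16 (median 1.23) at low levels, Cd3g at 0.663 and 16.6 FPKM, but with a pseudocount of 5 in 1 of 16, Cd3g. Interferon-stimulated genes were higher in 24 of 26 (median 1.75), with Ifi27l2a at 22.8 and 769. Mast cell genes were higher in 9 of 11 (median 1.88), with Mcpt4 at 10.4 and 182. Endothelial genes were higher in 10 of 16 (median 1.42) and pericyte genes in 9 of 11 (median 1.43).

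Dermal matrix genes did not move as a block from P3 to 10 weeks. Of 31 expressed members, 9 were higher and 4 lower. Ogn (17.3 to 260 FPKM), decorin, Dcn (205 to 2217) and dermatopontin, Dpt (73.9 to 668), small matrix proteins, were higher, and Tnc (23.3 to 2.05) and the fetal fibrillin Fbn2 (6.55 to 0.440) lower. The median of 0.39 lay above the random lists, a call that is lost with the mean or a minimum of 5 FPKM. Fibroblast lineage genes were higher in 9 of 16 and lower in 3 (median 1.22), with S100a4 higher (73.6 to 650 FPKM) and Dlk1 lower (10.9 to 0.306); with the mean this list lay inside the random lists. The pseudocount moved the totals of this comparison by over 1.5 times, to 1596 genes higher and 898 lower with 5, when 12 of 26 interferon-stimulated and 4 of 11 Langerhans and dendritic cell genes were still higher and 4 of 11 small proline-rich and 10 of 26 hair follicle signalling genes lower.

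**Figure D3:**
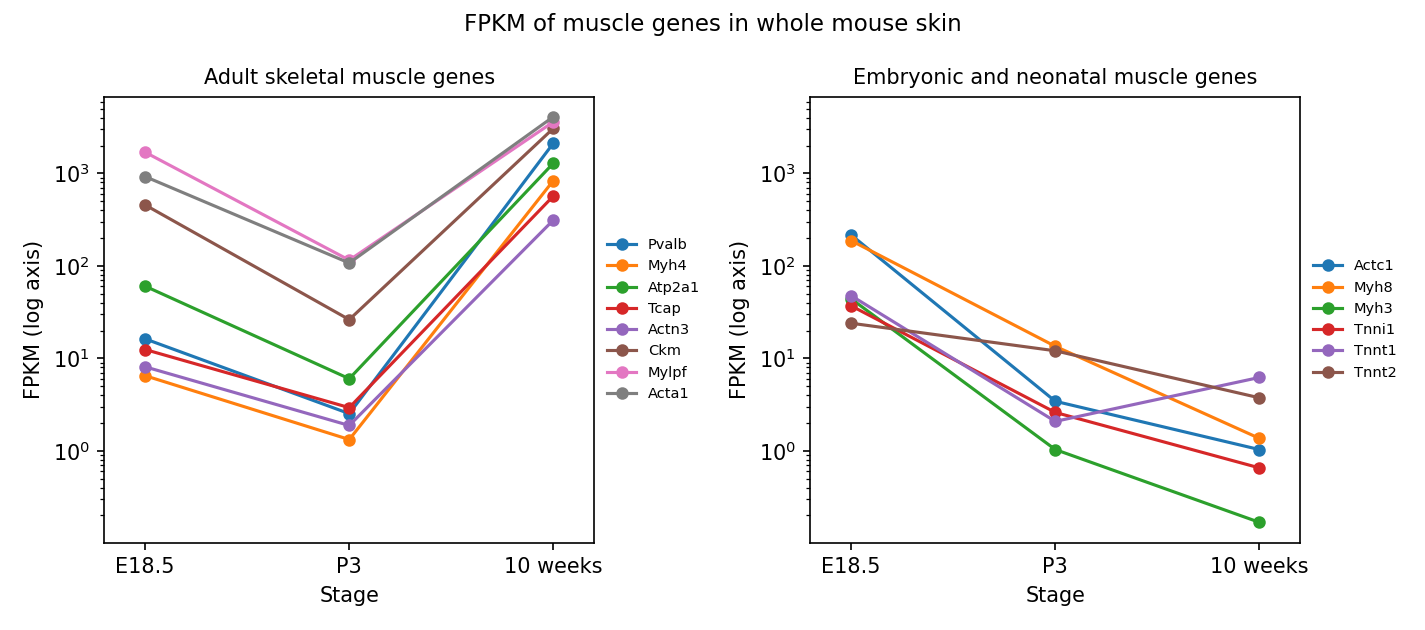
FPKM on a log axis at each of the 3 ages, 1 averaged value per point, for genes of adult skeletal muscle (left) and of embryonic and neonatal muscle (right). The adult genes dip at P3 and reach their highest values at 10 weeks (Acta1 4107 FPKM), whereas Actc1 goes from 216 FPKM at E18.5 to 1.03 at 10 weeks.

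Over the whole interval from E18.5 to 10 weeks, the adult skin had higher levels of macrophage, antigen presentation, interferon-stimulated, sebaceous and adult muscle genes and lower levels of proliferation, embryonic muscle and imprinted growth genes, while most epidermal lists lay inside the random lists. Of 14659 genes compared, 2358 were higher at 10 weeks and 1014 lower. The largest rises were Retnla (0.235 to 2905 FPKM), the beta-defensin Defb6 (0.104 to 1065), Ccl8 (0.285 to 660.5), Hamp2 (0.166 to 587), Serpinb6e (0.00518 to 139), the lectin Cd209d (0.505 to 196), Pvalb (16.3 to 2123) and H2-Aa (7.68 to 1014). Besides the stefin cluster, the largest falls included Dlk1 (163 to 0.306 FPKM), an inhibitor of fat cell differentiation, and Actc1 (216 to 1.03).

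Basal, suprabasal, p63 family and target, small proline-rich and lipid barrier lists lay inside the random lists, with medians of 0.16, -0.17, 0.21, -0.05 and 0.22. Single members still differed. Krt1 (log2 difference -3.78), Krt10 (-1.65) and Tgm3 (12.9 to 0.508 FPKM) were lower in the adult, and Krt77 (5.61), Sprr4 (11.5 to 515 FPKM), Elovl4 (67.1 to 308) and Klf4 (57.3 to 173) higher. The anchoring collagen of the basement membrane, Col7a1, was lower (log2 difference -1.82). The cornified-layer list lay below the random lists, with 14 of 29 members lower and 2 higher (median -0.79). Lce1d (234 to 32.6 FPKM) and Casp14 (66.8 to 8.39) were lower, and the protease inhibitor Spink5 was higher (41.4 to 126). Stress and periderm keratins were higher in 4 of 9 and lower in 1 (median 0.36, inside the random lists). Hair shaft genes were higher in 9 of 36 (median 0.56), a list call that is lost with the mean or a pseudocount of 5. Hair follicle signalling genes were lower in 11 of 26 (median -0.70), including Shh (11.2 to 0.982 FPKM), Edar (7.94 to 0.787) and Gli1 (34.9 to 6.64). Pigment cell genes were lower in 6 of 15 and higher in 2 (median -0.84). Hair follicle stem cell genes were higher in 4 of 17 and lower in 3 (median 0.01).

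Sebaceous gland genes were higher in 15 of 23 cases and lower in 0 (median 1.72), with Awat2 at 0.955 and 125 FPKM. Macrophage genes were higher in 17 of 18 (median 2.78) and 1 was lower, Cx3cr1 (4.43 to 1.21 FPKM). All 10 MHC class II genes (median 3.50) and all 15 class I genes (median 3.03) were higher. So were 10 of 11 Langerhans and dendritic cell genes (median 1.38, inside the random lists with a minimum of 5 FPKM), 11 of 16 T cell genes (median 1.23) and 20 of 26 interferon-stimulated genes (median 1.37). Adult muscle genes were higher in 27 of 29 and lower in 1 (median 2.68), and embryonic and neonatal muscle genes lower in 12 of 18 and higher in 1 (median -1.87). White adipocyte genes were higher in 7 of 21 (median 0.69), the leptin gene Lep going from 3.08 to 63.9 FPKM, and pericyte genes in 5 of 11 (median 0.93, lost with the mean). Endothelial (median 0.07), mast cell (-0.15), fibroblast lineage (0.12) and brown adipocyte (-0.23) lists lay inside the random lists; among them, the mast cell protease gene Mcpt4 was higher (21.2 to 182 FPKM) and Hdc lower (77.9 to 4.90). Proliferation genes were lower in 34 of 36 (median -2.13). Dermal matrix genes were lower in 11 of 30 and higher in 5 (median -0.73), the lower ones including elastin, Eln (188 to 51.1 FPKM), and Fbn2 (23.5 to 0.440), and the higher ones Dcn (572 to 2217). The share of called genes that were higher was 69.9%, and 56.9% with the upper quartile (1788 higher, 1354 lower) or 59.8% when scaled on the sum of the remaining genes (1880 and 1264). With a pseudocount of 5, 1274 genes were higher and 561 lower, and the call of Cx3cr1 is lost; 1 of 16 T cell, 3 of 11 Langerhans and dendritic cell and 8 of 26 interferon-stimulated genes were then higher, and 6 of 26 hair follicle signalling and 2 of 15 pigment cell genes lower. The Y-linked genes and Xist differ between these ages as given above, and 2298 genes were higher and 951 lower without chromosomes X and Y.

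Across all 3 ages, 1801 of 14653 genes (12.3%) were highest at 10 weeks by the 2-fold rule, 784 (5.35%) at P3 and 427 (2.91%) at E18.5. At P3, 812 genes were lowest, against 515 at 10 weeks and 359 at E18.5. The P3 peak held 26 of 28 cornified-layer, 15 of 18 suprabasal, 11 of 22 lipid barrier, 13 of 35 p63 family and target and 33 of 35 hair shaft genes. The P3 trough held 26 of 29 adult muscle, 14 of 21 white adipocyte, 11 of 18 macrophage and 9 of 16 endothelial genes. The 10-week peak held all 15 MHC class I and all 10 class II genes, 17 of 18 macrophage and 27 of 29 adult muscle genes, and the E18.5 peak 10 of 18 embryonic and neonatal muscle genes. With a pseudocount of 0.1 in place of 1, the genes lowest at P3 numbered 1484 and those lowest at E18.5 614.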

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

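Leaving out chromosomes X and Y, leaving out marker lists, counting failed values as 0 and, for lists, the pseudocount of 5 were chosen after the data had been seen, the other settings before. No list outside the random lists changed direction under a setting run. For lists, the pseudocounts keep the sign of each member, and the median of ratios shifted log2 ratios by -0.22 at most. Mainly the mean and the minimum of 5 FPKM thus left room for a reversal. A 2-fold difference of a single gene could not change direction, as a pseudocount keeps the sign and no scaling moved an age by over 0.30. For the genes this is therefore no test. Of the counts, shares and levels of Trp63 and keratins set against an alternative, 184 stayed within 1.5 times the main value and 21 did not. All 3 scalings, the minimum of 5 FPKM, rows with 1 symbol, removal of short RNA and low-data genes and the 3 added settings are among the former; the marker lists removed left 1392 and 1278 genes (P3 over E18.5), 2772 and 1450 (10 weeks over P3) and 2262 and 984 (10 weeks over E18.5). Using no minimum changed no count, which the pseudocount of 1 ensures, so this setting tests nothing. Thresholds of 1.5-fold and 4-fold moved every count, by construction. From E18.5 to P3, 2803 genes were higher and 2654 lower at 1.5-fold, and 348 and 358 at 4-fold. From P3 to 10 weeks these were 4503 and 2599, and 1105 and 489; from E18.5 to 10 weeks, 4178 and 1692, and 718 and 392. A pseudocount of 5, which shrinks differences of low genes, left 842 higher and 626 lower, 1596 and 898, and 1274 and 561 in the same order. With 0.1, 2155 genes were lower at P3 than at E18.5, 1484 were lowest at P3 and 614 lowest at E18.5, since this pseudocount enlarges differences near 0. Of 89 list results outside the random lists, of 123, 78 stayed outside under each alternative that gave a value and 11 did not: 1 was lost with the median of ratios, 4 with the minimum of 5 FPKM, 9 with the mean, 5 with a pseudocount of 5 and 0 with 0.1. The class I presentation list at P3 over E18.5 was lost with 4 of these, and with 2 the interferon-stimulated and hair follicle stem cell lists (P3 over E18.5), the dermal matrix and brown adipocyte lists (10 weeks over P3) and the hair shaft list (10 weeks over E18.5). Of 517 differences of named genes past 2-fold, 13 fell below it with the median of ratios, 19 with the upper quartile, 14 with the sum of the remaining genes, 71 with a pseudocount of 5 and 0 with 0.1. Under the alternatives 77 list medians moved by over 1.5-fold and 532 did not, and 397 differences of named genes did, all of these with a changed pseudocount, and 2518 did not. Leaving out each replicate was not run, as there is 1 averaged value per age. No paired analysis was possible because the tables carry no replicate values. Depth is unknown, so the counting error of a low FPKM cannot be given.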

Other observations

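Several lists outside the main tissue layers also differed between ages. The stretch of chromosome 12 between Meg3 and the end of Mirg (110818443 to 110987667) held 28 microRNA rows at or above 1 FPKM at any age. Of these, 27 had their highest value at E18.5, 19 were listed at 0 at P3 and 27 at 10 weeks. Many of the rows carry the same coordinates as the longer transcripts Rtl1, Rian or Mirg. Reads of those transcripts can be counted in them, so that a course shared with them is no separate observation. Mir127 stood at 222 and 9.48 FPKM at E18.5 and P3, and Mir485 at 215 and 49.0; these rows were chosen after their values were seen, and FPKM of such short genes is unreliable. Cholesterol synthesis genes were higher after birth, 11 of 21 at P3 against E18.5 with 0 lower (median 1.04; 6 with a pseudocount of 5), and 7 were lower again at 10 weeks with 0 higher (median -0.80). Over the whole interval 3 were higher and 0 lower (median 0.03). Oxidative phosphorylation genes had medians of -0.65 at P3 and 0.56 from P3 to 10 weeks, beyond the random lists. Only 3 of 42 passed 2-fold in the first and 2 in the second, and the net median was -0.12. The adult muscle (-2.90 and 5.74) and brown adipocyte (-2.19 and 1.14) lists moved in the same directions. The second brown adipocyte call is lost with the mean or a pseudocount of 5. Its largest rises were in Cox8b (17.2 to 402 FPKM) and Cox7a1 (14.9 to 198), whereas Ucp1 was lower again (2.54 to 0.0308). Over the whole interval the adult muscle list was at 2.68, and a link between these lists was not tested. Ribosomal protein genes had medians of -0.07, -0.19 and -0.23 in the 3 comparisons, the last below the random lists, and Rps27 alone passed 2-fold, a gene with a second row that shares its reads. The housekeeping list had medians of 0.06, -0.07 and -0.03, but Gapdh stood at 1237, 292 and 942 FPKM.

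The antimicrobial and immediate early lists lay above the random lists at 10 weeks over E18.5, though members of the first went both ways. Antimicrobial and alarmin genes were higher at P3 in 11 of 21 cases and lower in 2 (median 1.12), split from P3 to 10 weeks (9 higher, 7 lower, median -0.13), and ended with 12 higher and 5 lower than at E18.5 (median 1.30; 7 and 4 with a pseudocount of 5). Defb6 stood at 0.104, 61.8 and 1065 FPKM, the alarmin cytokine Il33 at 1.39, 2.82 and 29.3, and Il1f6, an epithelial interleukin, at 11.5, 38.4 and 0.457. Immediate early genes were higher in 13 of 19 cases at P3 (median 1.41) and in 11 from P3 to 10 weeks, with 3 lower (median 1.45). Over the whole interval 14 were higher and 0 lower (median 2.70), with Fos at 7.93, 57.9 and 649 FPKM and Egr1 at 12.5, 81.5 and 279. Tissue handling also induces these genes. Circadian clock genes did not pass 2-fold from E18.5 to P3 (0 of 16, median 0.25), but 8 were higher and 1 lower at 10 weeks than at P3 (median 1.00), and 7 higher than at E18.5 (median 0.81), with Dbp at 2.75, 2.56 and 38.9 FPKM and Nr1d1 at 4.76, 6.96 and 59.7. The hour of sampling is not given in the sources used here. Schwann cell and nerve genes went both ways at P3 (3 of 14 higher, 3 lower, median 0.13), then 9 were higher and 1 lower at 10 weeks than at P3 (median 1.39; 5 and 0 with a pseudocount of 5) and likewise than at E18.5 (median 1.48). The myelin gene Mbp (9.38, 14.0 and 107 FPKM) was among those higher at 10 weeks, and the growth-cone gene Gap43 was lower at each step (22.5, 5.62 and 1.11), the second call being lost with a pseudocount of 5. Interferon-stimulated genes had a median of -0.50 at P3, with 1 of 26 higher and 3 lower, before their higher values in the adult. T cell genes had a median of 0.05 at P3. Of 10 neutrophil genes, 0 were higher and 2 lower at P3 (median -0.22, inside the random lists). From P3 to 10 weeks 4 were higher and 3 lower (median -0.25, inside), or 2 and 1 with a pseudocount of 5. Over the whole interval 3 were higher and 4 lower (median -0.38, below the random lists), or 2 and 3 with a pseudocount of 5. S100a8, among the higher, stood at 20.1, 24.4 and 135 FPKM. The lower ones included Stfa1 (354 FPKM at E18.5, listed at 0 at 10 weeks), of the stefin cluster with shared reads. Ngp was also lower, a call lost with a pseudocount of 5. Of 3 expressed B and plasma cell genes, 2 were higher in the adult than at P3 and than at E18.5, Igj and Tnfrsf17, but neither with a pseudocount of 5, and the list lay inside the random lists in all 3 comparisons. Erythroid genes were lower in 5 of 7 cases at P3 (median -1.44) and in 6 of 7 from E18.5 to 10 weeks (median -1.43), with a median of -0.09 from P3 to 10 weeks. The shared alpha globin row was at 1574 FPKM at E18.5 and listed at 0 at 10 weeks although Hbb-b2 was still at 420 FPKM, so that the alpha globin values are doubtful.

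The tests that follow were chosen only after the result was seen, except those on length and GC content. The first pattern is that 83 epidermal list members had a median of 1.57 at P3 over E18.5, and 141 stromal members one of -1.48. The stromal members were of muscle, matrix, white fat, vessel, macrophage and mast cell lists. Lists left out of this set included brown adipocyte (median -2.19), fibroblast lineage (-0.89), pericyte (-0.59) and Schwann and nerve (0.13). A length or GC trend as the whole cause is argued against: with a linear trend on both removed, the gap between the medians was 3.17 (95% bootstrap interval over members 2.86 to 3.34), against 3.05 before. An equal loss of all non-epithelial tissue as the whole cause is also argued against, since the muscle median minus the matrix median was -1.71. The intervals over members were -3.22 to -2.00 and -1.35 to -0.90 and hold no spread between animals. An equal loss together with a change of expression within a tissue is not excluded. A shallower piece of skin at P3, with less of the deep muscle and fat, cannot be told apart from a change within the tissue: muscle lay lower than matrix, but fat differed from it by -0.23 with overlapping intervals. The age of the animals, with the growth of epidermis and hair after birth, stays open and untested beyond these values.

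The second pattern is the expression of 4 Y-linked genes at E18.5 and their near absence at P3 and 10 weeks. Male animals among the E18.5 animals only is an explanation that Xist bears out, as it was higher at both later ages, by at least 5.97 (log2). With Xist at 0.0433 FPKM at E18.5, there was little sign of female RNA in that library. By these genes, the E18.5 library held male RNA, and those of P3 and 10 weeks held female RNA. Sex, age and library are therefore confounded in both comparisons with E18.5, but not by these genes in that of P3 with 10 weeks. X-linked genes as a whole differed little, with a median of -0.13 over 479 genes from E18.5 to P3 against 0.04 for the others. This median cannot speak to sex, because X inactivation evens out the dose of most X-linked genes between the sexes. Any effect of sex on autosomal genes also stays when chromosomes X and Y are left out. No biological explanation by age was tested for this pattern.

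The third pattern is that adult muscle genes were higher at 10 weeks than at E18.5. More muscle in the adult piece as the whole cause is argued against, because it would raise both muscle lists alike. The adult list lay 4.55 above the embryonic and neonatal list, with bootstrap intervals over members of 2.26 to 3.24 and -3.60 to -0.39. Both medians had been seen before, so this shows only that the mix of adult and embryonic muscle transcripts differed between these ages. A length or GC trend is argued against as well, since the adult median was 2.75 (2.28 to 2.97) with the trend removed. A switch from embryonic to adult isoforms within the muscle cannot be told apart from other changes by the test made here, which is void: it uses 4 ratios of members of the same 2 lists, so that their rise, by at least 41.1-fold, restates the pattern. As values, adult over developmental myosin heavy chain was at 0.0754, 0.322 and 711 at the 3 ages, fast over slow troponin I at 15.6, 19.7 and 4275, skeletal over cardiac actin at 4.28, 31.3 and 3980 and fast over cardiac troponin T at 22.9, 4.18 and 943, with low denominators in the adult. A larger muscle share as part of the cause and the age of the animals stay open.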
